A study of Mus musculus with 7 samples.

How the data were processed

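RNA-seq was analysed for 7 spleen libraries of female mice, 3 in a group named IL13RA1KO_DKO here and 4 in a group named DKO. Per the labels, RNA was extracted with RNeasy Plus columns, and libraries were made from poly-A RNA with the SMART-Seq v3 Ultra Low Input kit followed by Nextera preparation, which does not mark strand. The authors deposited whole-number counts per Ensembl gene, not normalized, with 1 column per library. The submitters' processing notes name the mm10 build, FastQC and edgeR, without versions. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Groups and replicate numbers were taken from the sample descriptions, in which DKO replicates are numbered from 1 while their titles start from Rep2.

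The table held 54752 gene IDs, of which 54723 were matched to a symbol in GENCODE mouse release 21 (GRCm38, the assembly of mm10) with the version of the ID ignored, and 27405 had a count in at least 1 library. Coordinates are from that annotation. Total counts per library were 34580334, 27712022 and 31299910 in IL13RA1KO_DKO replicates 1 to 3 and 23557752, 22624715, 27985958 and 31496058 in DKO replicates 1 to 4. No columns were identical, and replicates of a group differed by far more than sampling noise (chi-square per degree of freedom from 46.2 to 174 over genes). Ighm had the most counts in every library, 3.42 to 6.70% of the total, and immunoglobulin genes together took 7.80 to 13.9%. Y-linked genes had 0 to 5 counts per library.

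Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total 15), robust quasi-likelihood fits and a two-sided quasi-likelihood F test between the groups, with no covariates. The threshold was a Benjamini-Hochberg adjusted p under 0.05, and a second count asked for an absolute log2 fold change of at least 1. CPM values are counts scaled by the TMM-adjusted library size and given as mean ± SD. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over lists, and again with an estimated correlation and with fry, a directional test of each list by itself. Of 37 lists 34 had at least 5 tested members. Library distances and heavy chain shares were tested with exact permutation tests (scipy 1.17.1), whose smallest p over the 35 splits is 0.0286 one-sided and 0.0571 two-sided. The groups, the test, the lists, the naming rule and 19 of 24 alternative settings of the gene tests were chosen before the data were examined. The 5 others were chosen after seeing the data. They are GC offsets, GC and length offsets, a macrophage score covariate, GC offsets without DKO replicate 2, and GC offsets with the covariate.

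The genes named include Il13ra1, Def6 and Swap70. They include the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. To these were added up to 4 members with the smallest adjusted p of each list described, and Itgax, Itgam, Tbx21, Zeb2 and Fcrl5. The rule for the largest changes left out clone-named genes, pseudogenes and receptor segments, and its other conditions were met by 506 genes higher and 1006 lower. Of the 34 tested lists 20 are described. They are the 13 past the threshold and 7 more chosen after the results were seen, and 5 further lists were dropped at that stage, in part for length. Some genes that the rule takes are not reported here. Gapdh is named in the closing observations as a gene chosen after its values were seen. So were Cd3d, Cd3g, Lck, Lat, Trac and Trbc2, named with the T cell list. Adgre1, Ly6c2, Mpeg1 and Cebpb of the macrophage list and Prf1, Klrd1 and Il2rb of the NK cell list were chosen in the same way.

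GC content and length were taken from the longest transcript and the exons of each gene, with values for 99.97% of tested genes, and the offsets are per-library splines with 5 degrees of freedom. Near-identical stretches of at least 100 bases at 95% identity in other annotated transcripts were sought with BLAST+ 2.17.0. Alternatives covered DESeq2 1.42.0, limma-voom with quality weights, other normalizations and filters, each library left out in turn, the replicate number as a block, and DKO libraries of 1 set of title codes at a time. Counts of alternatives given beside a gene leave out the 2 settings with the macrophage covariate.

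The gene tests, camera and the GC offsets were tested on simulated data with 13544 genes drawn from the means and library sizes of this comparison. For the gene test and camera 200 genes were changed and the glycolysis list was raised 1.5-fold. The edgeR test recovered 10.4% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 90.9% of those changed 4-fold. Of its calls 8.40% were unchanged genes. Most changes of 1.5-fold were thus missed in the simulation. It changed far fewer genes than the 2196 called in the real data, which makes the adjusted threshold stricter, so these shares do not carry over to the real comparison. The offsets took a simulated GC trend from a Spearman correlation of 0.628 to 0.00186. Reads without molecular identifiers are not independent molecules, so that counts understate the error of a single library.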

Results

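Spleen RNA from female mice was measured by RNA-seq in 7 libraries that fall into 2 groups. The 4 DKO libraries came from mice labelled deficient in DEF6 and SWAP-70, a related pair of signalling proteins of lymphocytes. The 3 other libraries, labelled IL13RA1KO_DKO here, came from mice whose sample titles add a knockout written IL13R1KO. It was taken to mean Il13ra1. This gene encodes the IL-13 receptor alpha 1 chain, which pairs with the IL-4 receptor alpha chain to bind IL-13 and IL-4. The series title places the comparison in the expansion of ABCs, the age-associated B cells that accumulate in lupus models. The DKO titles carry the tag ABC and those of the other group do not, and no label states that cells were sorted. The genotype tag and the sample descriptions of the other group name IL-13 in place of its receptor, so the identity of the further knockout is assumed. Genes shared by all B cells averaged 9.32 to 9.83 log2 CPM over the 7 libraries and T cell genes 0.204 to 1.94. These levels argue against RNA of unsorted spleen. Total counts were 27712022 to 34580334 in the libraries labelled IL13RA1KO_DKO and 22624715 to 31496058 in the DKO libraries. The sample titles carry a code whose meaning the labels do not give. The 3 libraries labelled IL13RA1KO_DKO share a code, DKO replicates 3 and 4 share another, and DKO replicates 1 and 2 each have their own. No code occurs in both groups, so the code and the genotype cannot be told apart. Letters before the code, MM in all DKO titles and ZC in the others, also part the groups, and their meaning is not given. The labels do not say whether libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

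The gene that names the contrast, Il13ra1, was detected at similar low levels in both groups. It had 6.13, 4.90 and 4.83 CPM in the libraries labelled IL13RA1KO_DKO (mean 5.29 ± 0.734 SD, n = 3) and 4.21, 3.95, 6.24 and 10.2 CPM in the DKO libraries (6.15 ± 2.90 SD, n = 4), from 91 to 296 counts per library. Its log2 fold change was -0.22 (SE 0.34, edgeR adjusted p = 0.684). Counts per gene do not show which exons were read, so a deletion that leaves part of the transcript would not be seen, and these counts do not check the label. Il13ra1 (ENSMUSG00000017057) lies on the plus strand of chromosome X from 36112110 to 36171259 in mm10. Def6 (ENSMUSG00000002257, chromosome 17 from 28207778 to 28228608, plus strand), disrupted by a gene trap in both groups, had 4.64 ± 1.19 CPM against 8.23 ± 2.83 CPM (log2 fold change -0.82, SE 0.29, edgeR adjusted p = 0.0884). Swap70 (ENSMUSG00000031015, chromosome 7 from 110221711 to 110283506, plus strand) kept 209 ± 2.36 CPM against 224 ± 32.6 CPM in mice labelled deficient in both groups (log2 fold change -0.10, SE 0.14, edgeR adjusted p = 0.648). As a targeted gene Def6 passed with DESeq2 (log2 fold change -0.84), without a low-count filter (-0.84) and with GC offsets and no DKO replicate 2 (-0.88). The fold change of Il13ra1 changed sign without DKO replicate 4 (0.13).

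The 7 libraries separated by group. The mean distance between libraries of different groups was 2.98 (leading log2 fold change over 500 genes) against 2.10 within groups, a difference of 0.88. In an exact one-sided permutation test over the 35 splits into 3 and 4 libraries this gave p = 0.0286, the smallest p the design allows. DKO replicates 3 and 4, which share a title code, were the closest pair of all (1.61), against 2.245 to 2.457 for the other DKO pairs. In each group a library differed in its distance to the other group. IL13RA1KO_DKO replicate 2 lay farthest from the DKO libraries, and without it the difference was 0.53. DKO replicate 2 lay nearest to the other group, and without it the difference was 1.16. With any library left out the design cannot reach the threshold, and the exact p was 0.0667 or 0.100, the smallest possible there.

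**Figure D1:**
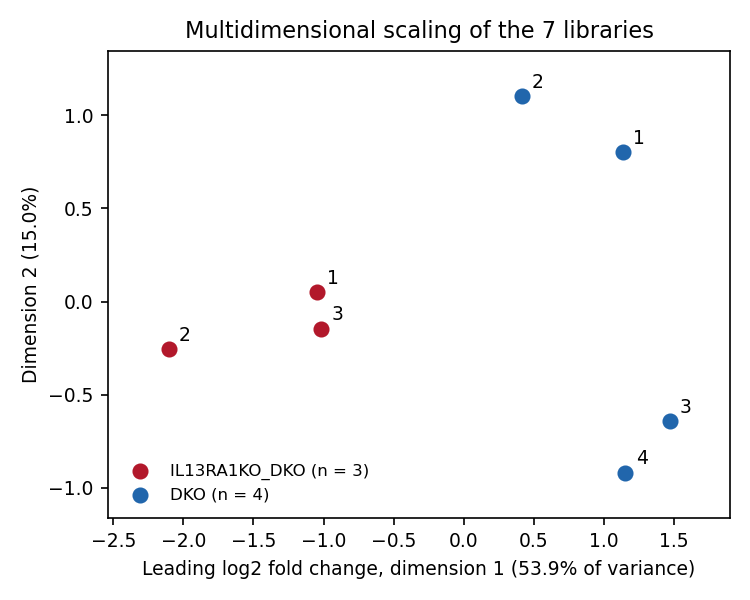
Multidimensional scaling of the 7 libraries, with each point a library marked by its replicate number and coloured by group, and axes in leading log2 fold change. Dimension 1 holds 53.9% of the variance and separates the groups, with IL13RA1KO_DKO replicate 2 at -2.11 and DKO replicate 2 at 0.41, and dimension 2 holds 15.0%.

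Gene expression differed widely between the groups, and Gzma, Apobr and Ccl5 led the 10 genes named for the largest rises. Gzma, which encodes a cytotoxic granule protease, rose from 0.834 ± 0.627 CPM in DKO (SD, n = 4) to 33.1 ± 34.3 CPM in the libraries labelled IL13RA1KO_DKO (SD, n = 3), a log2 fold change of 5.34 (SE 0.87, edgeR adjusted p = 0.00776). Without IL13RA1KO_DKO replicate 2 the log2 fold change of Gzma was 4.03. Apobr, a lipoprotein receptor of myeloid cells, rose from 1.00 ± 0.479 to 16.8 ± 9.11 CPM (log2 fold change 4.07, SE 0.47, edgeR adjusted p = 0.0024). The chemokine gene Ccl5 rose from 1.67 ± 0.367 to 26.7 ± 26.9 CPM (4.00, SE 0.65, edgeR adjusted p = 0.00722, and 2.76 without IL13RA1KO_DKO replicate 2). The largest falls included the ribosomal protein gene Rps25 (169 ± 140 to 17.9 ± 2.89 CPM) and the lysophospholipid receptor gene P2ry10 (215 ± 49.2 to 62.4 ± 8.62 CPM, log2 fold change -1.78, SE 0.20, edgeR adjusted p = 0.0024). In all, 2196 of 13769 tested genes passed the edgeR quasi-likelihood test, 1017 of them higher and 1179 lower in the libraries labelled IL13RA1KO_DKO. Of these, 994 did so with an absolute log2 fold change of at least 1 (758 higher and 236 lower).

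The other large rises were in Adam23 (log2 fold change 3.91), the prostacyclin synthase gene Ptgis (3.56), the heparan sulfate sulfotransferase gene Hs3st2 (3.20), the cytotoxic granule gene Nkg7 (3.18), the chemerin receptor gene Cmklr1 (3.16), Nav1 (3.16) and the transporter gene Abcc3 (3.13). Nkg7 had 1.96 without IL13RA1KO_DKO replicate 2, and Nav1 lost its call in 2 of 22 alternatives. The other large falls were in mt-Tc (-3.30), Thsd7a (-2.57), the leukaemia inhibitory factor receptor gene Lifr (-2.20), Ramac (-1.81), Tm2d1 (-1.76), and the zinc finger genes Zxdb (-1.75), Zfp760 (-1.73) and Zfp758 (-1.71). Rps25 had a log2 fold change of -3.24 (SE 0.78, edgeR adjusted p = 0.0305) but differed within DKO, with 324 and 252 CPM in replicates 1 and 2 against 44.6 and 56.8 CPM in replicates 3 and 4, which share a title code. Each of these 20 genes had library values that did not overlap between the groups, as the choice of named genes required. Rps25, P2ry10, Ramac, Tm2d1, Zxdb and Nav1 share a stretch of at least 100 bases at 95% identity with another annotated gene, so their counts are uncertain. So are those of mt-Tc, a short tRNA gene cut from a longer mitochondrial precursor (M from 5192 to 5257, minus strand). Without IL13RA1KO_DKO replicate 2 the calls of Ptgis, Rps25, Thsd7a and Lifr were lost (edgeR adjusted p = 0.127, 0.127, 0.0852 and 0.157). Rps25, Thsd7a and Lifr also lost theirs without either of the other IL13RA1KO_DKO replicates, Rps25 and Lifr without DKO replicate 2, and Ptgis and Lifr without DKO replicate 4, with edgeR adjusted p from 0.055 to 0.113. Lifr lost its call with GC offsets too (edgeR adjusted p = 0.0553).

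Genes that fell had a lower GC content than genes that rose, with medians of 42.4% and 51.5%. Across 11888 protein-coding genes the log2 fold change and GC content had a Spearman correlation of 0.332, over genes that are not independent replicates. In the decile of genes with the lowest GC content, 454 of 1189 fell and the median log2 fold change was -0.46, while 15 of 1189 fell in the decile with the highest. With per-sample GC offsets 1749 genes passed the edgeR test, 903 higher and 846 lower, and 615 of the 1179 lower genes were still lower. Of the genes with an absolute log2 fold change of at least 1, 706 were then higher and 111 lower, and 741 were higher and 90 lower with GC and length offsets.

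**Figure D2:**
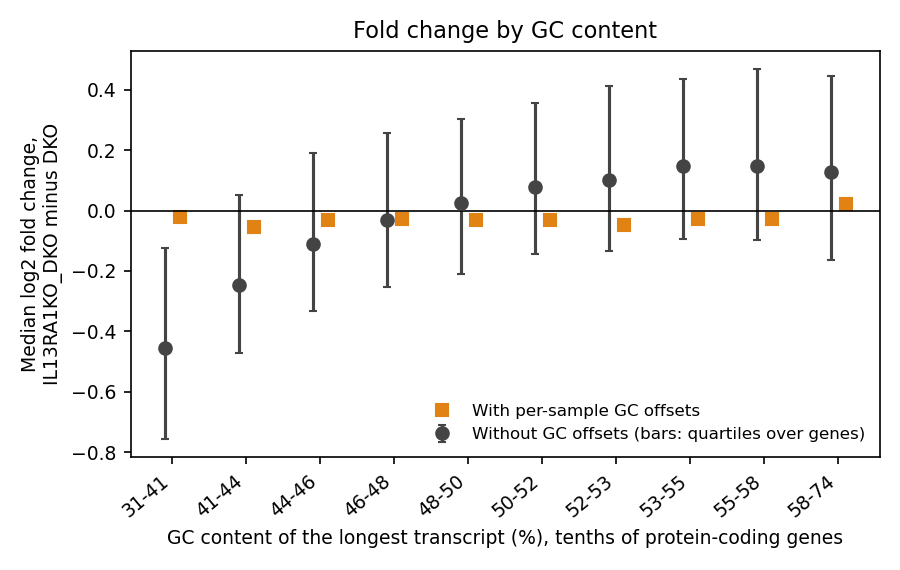
Median log2 fold change (IL13RA1KO_DKO minus DKO, y axis) in deciles of protein-coding genes ordered by the GC content of the longest transcript (x axis, %), without GC offsets (circles, bars from the lower to the upper quartile over genes) and with them (squares). Without offsets the median runs from -0.46 in the lowest decile to 0.13 in the highest, and with offsets it is -0.02 and 0.02 there.

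The number of genes past the edgeR threshold was 899 without IL13RA1KO_DKO replicate 2, 1368 without IL13RA1KO_DKO replicate 3 and 4346 without DKO replicate 2, 4601 against DKO replicates 3 and 4 alone and 868 against DKO replicates 1 and 2 alone. It was 4770 with limma-voom, 1456 with a stricter low-count filter, and 0 with the macrophage score as a covariate, where 449 genes had an unadjusted p under 0.05. That score had a correlation of 0.927 with the group over the 7 libraries. Fits with it leave little of the group difference to estimate and cannot show what macrophage RNA accounts for. The share of genes past the threshold that were higher was 46.3% with TMM normalization, 56.6% with upper quartile normalization and 57.4% with total counts.

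Most genes of monocytes and macrophages rose in the libraries labelled IL13RA1KO_DKO. Of 24 such genes 20 rose and none fell (21 rose when adjusted over the list alone). The median log2 fold change of the list was 2.24 (camera adjusted p = 6.59e-23, and adjusted p = 0.524 with an estimated correlation). Cd5l, a secreted macrophage protein, rose from 85.2 ± 14.4 to 306 ± 59.2 CPM (log2 fold change 1.85, SE 0.17, edgeR adjusted p = 0.0019). Cd68, a lysosomal glycoprotein of macrophages, rose from 28.1 ± 5.55 to 128 ± 48.4 CPM (2.19, SE 0.25, edgeR adjusted p = 0.0024). The haem-degrading enzyme gene Hmox1 (2.74) rose as well. Other members moved little or the other way, with log2 fold changes of 0.18 for Adgre1, 0.17 for Ly6c2, 0.76 for Mpeg1 and -0.65 for Cebpb. The mean log2 CPM of the list was 6.64, 7.46 and 6.27 in the libraries labelled IL13RA1KO_DKO and 4.46 to 5.12 in the DKO libraries. Genes for the binding and engulfment of apoptotic cells moved with them, with 11 of 24 higher and 2 lower (12 and 4 when adjusted over the list alone). They had a median of 1.29 and a camera adjusted p of 1.58e-05 (adjusted p = 0.524 with an estimated correlation). Among them were the receptor genes Axl (log2 fold change 2.63, also a member of the macrophage list), Mertk (2.91) and Stab2 (2.67) and the oxysterol-sensing nuclear receptor gene Nr1h3 (2.17).

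Markers of NK cells were also higher, as were some T cell genes. Of 14 NK cell genes 11 rose and none fell, the same numbers as when adjusted over the list alone. The median log2 fold change was 3.95 (camera adjusted p = 3.12e-09, and adjusted p = 0.589 with an estimated correlation). Prf1, Klrd1 and Il2rb moved little, with log2 fold changes of -0.12, 0.35 and 0.19. The NK receptor genes Klre1 (5.33, SE 0.81, edgeR adjusted p = 0.00396), Ncr1 (5.17) and Klrk1 (3.38) and the transcription factor gene Eomes (4.59) rose from DKO levels of 0.0697 to 0.892 CPM to 2.95 to 9.31 CPM. Of 14 T cell genes 4 rose (5 when adjusted over the list alone), with a median of 0.89 (camera adjusted p = 0.00911, and adjusted p = 0.589 with an estimated correlation). Cd4 rose from 1.69 ± 0.649 to 12.9 ± 5.58 CPM (log2 fold change 2.93, SE 0.39, edgeR adjusted p = 0.00332). Cd247 (3.67), Icos (1.44) and Cd8a (2.21) stayed at 2.18 CPM or less on average in either group. The other 10 T cell genes were not called. Among them Cd3d had a log2 fold change of 0.19, Cd3g 0.37, Lck -0.09, Lat 0.003, Trac 1.14 and Trbc2 1.60. Replicate 2 had the highest NK and T cell list means of the libraries labelled IL13RA1KO_DKO, 3.99 and 1.94 log2 CPM. Without it the NK cell list had a median of 2.76 (camera adjusted p = 4.85e-17), and the T cell list had a median of 0.34 (camera adjusted p = 0.05) and the calls of Icos and Cd8a were lost (edgeR adjusted p = 0.138 and 0.189). Klre1, Ncr1, Klrk1, Eomes and Cd247 then had log2 fold changes of 4.14, 3.88, 2.53, 3.68 and 2.28. The T cell list also lost its call without DKO replicate 2, against DKO replicates 3 and 4 alone and with limma-voom (camera adjusted p = 0.0592, 0.184 and 0.0588). Icos lost its call without any library but DKO replicate 2 and Cd8a without any but IL13RA1KO_DKO replicate 3 and with GC offsets (edgeR adjusted p = 0.0592). Calls were also lost for Klre1, Ncr1, Klrk1, Eomes, Gzma, Ccl5, Nkg7 and Cd247 against DKO replicates 1 and 2 alone (edgeR adjusted p from 0.053 to 0.109), and for Ccl5, Nkg7 and Cd247 also against DKO replicates 3 and 4 alone (edgeR adjusted p from 0.0594 to 0.0833).

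Erythroid and neutrophil genes had high medians at low levels. Of 10 erythroid genes 3 rose (7 when adjusted over the list alone), with a median log2 fold change of 2.26 (camera adjusted p = 9.73e-04, and adjusted p = 0.589 with an estimated correlation). These were the anion exchanger gene Slc4a1 (2.85), the carbonic anhydrase gene Car2 (1.42) and the globin gene Hbb-bt (2.30), which averaged 3.02 to 8.62 CPM in the libraries labelled IL13RA1KO_DKO. Alas2, of haem synthesis, had 2.21 (edgeR adjusted p = 0.0529). Of 11 neutrophil genes 2 rose, the cytokine receptor gene Csf3r (2.93) and the chemokine receptor gene Cxcr2 (3.10), and 4 rose when adjusted over the list alone. The list had a median of 2.32 (camera adjusted p = 0.0116, and adjusted p = 0.765 with an estimated correlation). Il1b and Mmp9 had log2 fold changes of 2.15 and 3.46 (edgeR adjusted p = 0.0573 and 0.0819). Il1b passed without IL13RA1KO_DKO replicate 3 or DKO replicate 1 (0.0275 each) and Mmp9 without IL13RA1KO_DKO replicate 1 (0.0472). Without IL13RA1KO_DKO replicate 2 the neutrophil list had a median of -0.24 (camera adjusted p = 0.157), and it lost its call without DKO replicate 2, against DKO replicates 3 and 4 alone and with limma-voom (camera adjusted p = 0.119, 0.44 and 0.0905). The erythroid list had a median of 1.35 without IL13RA1KO_DKO replicate 2 (camera adjusted p = 0.00501). The calls of Slc4a1, Car2, Hbb-bt and Cxcr2 were lost without IL13RA1KO_DKO replicate 2 (edgeR adjusted p = 0.0945, 0.139, 0.155 and 0.232). Calls were also lost without DKO replicate 3 for all 4, without DKO replicate 1 for Car2, Hbb-bt and Cxcr2, without DKO replicate 2 for Hbb-bt and Cxcr2, and without DKO replicate 4 for Cxcr2. The same held without IL13RA1KO_DKO replicate 1 for Car2 and replicate 3 for Slc4a1 and Hbb-bt (edgeR adjusted p from 0.0522 to 0.102 over both). Cxcr2 lost its call with GC offsets as well (edgeR adjusted p = 0.0502). Csf3r, Cxcr2 and Hbb-bt share a near-identical stretch with another gene.

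**Figure D3:**
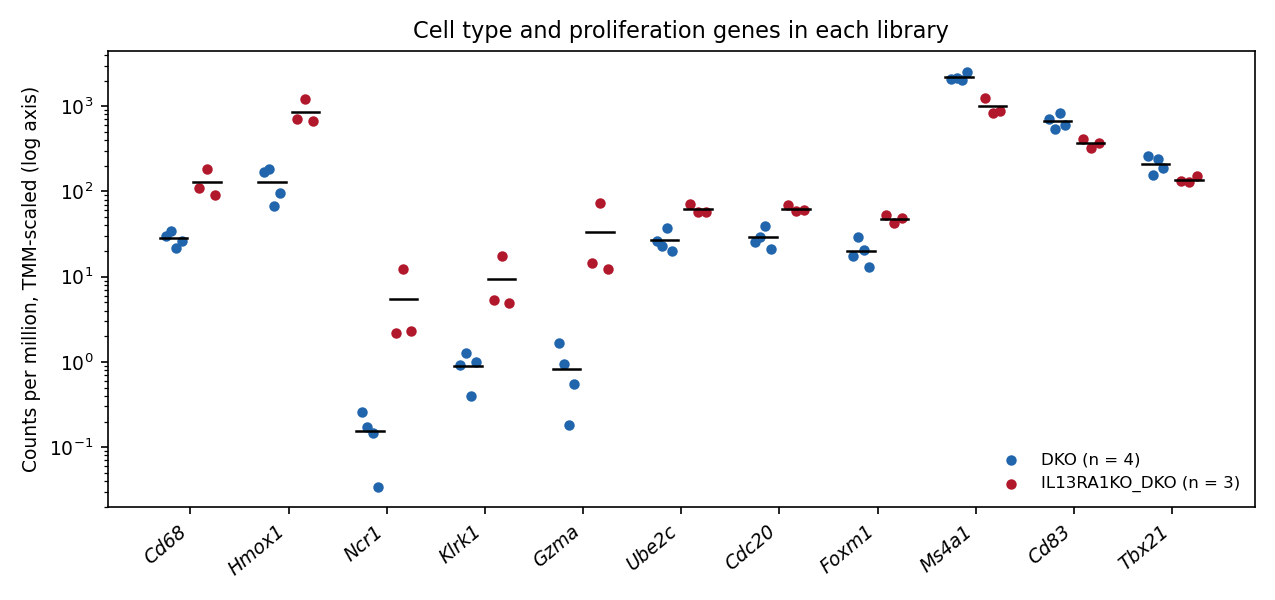
CPM values (TMM-scaled, log axis) of macrophage (Cd68, Hmox1), NK cell (Ncr1, Klrk1, Gzma), proliferation (Ube2c, Cdc20, Foxm1) and B cell genes (Ms4a1, Cd83, Tbx21) in each library, with points for libraries and lines for group means (DKO n = 4, IL13RA1KO_DKO n = 3). For each gene shown the library values of the groups do not overlap, and Gzma reaches 72.7 CPM in IL13RA1KO_DKO replicate 2 against 14.4 and 12.3 CPM in replicates 1 and 3. Itgax, Itgam, Zeb2 and Fcrl5, whose values overlap between the groups, are not shown.

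Cell cycle genes were higher in the libraries labelled IL13RA1KO_DKO. All 34 genes of the proliferation list had positive log2 fold changes and 19 rose (27 when adjusted over the list alone). The median was 0.81 (camera adjusted p = 2.82e-13, and adjusted p = 0.589 with an estimated correlation). Ube2c and Cdc20, which act with the anaphase-promoting complex, rose from 26.7 ± 7.61 to 61.6 ± 8.14 CPM (log2 fold change 1.21, SE 0.21, edgeR adjusted p = 0.00616) and from 28.9 ± 8.0 to 62.9 ± 5.34 CPM (1.12, SE 0.20, edgeR adjusted p = 0.00677). The mitotic kinase gene Aurka (1.04) and the cell cycle transcription factor gene Foxm1 (1.27, with a near-identical stretch in 1 other gene) rose too. The mean log2 CPM of the list was 6.15 to 6.50 in the libraries labelled IL13RA1KO_DKO, which were also those with the higher macrophage genes, and 4.87 to 5.66 in the DKO libraries. Within the groups the order differed. IL13RA1KO_DKO replicate 2 had the highest macrophage mean (7.46) and the lowest proliferation mean (6.15) of its group. DKO replicate 3 had the lowest macrophage mean (4.46) and the highest proliferation mean (5.66) of its own.

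Genes shared by all B cells were lower in the libraries labelled IL13RA1KO_DKO, where the macrophage and NK cell genes were higher. Of 19 such genes 8 fell and none rose (9 fell when adjusted over the list alone). The median log2 fold change was -0.33 (camera adjusted p = 9.09e-04, and adjusted p = 0.524 with an estimated correlation). Ms4a1, which encodes CD20, fell from 2202 ± 238 to 993 ± 233 CPM (log2 fold change -1.15, SE 0.17, edgeR adjusted p = 0.00401). The activation marker gene Cd83 (-0.86), the B cell scaffold gene Bank1 (-0.60) and Fcrla (-0.53) fell as well, with edgeR adjusted p from 0.00796 to 0.0238. Genes of antigen presentation by MHC class II had 3 of 19 lower, also 3 when adjusted over the list alone. Their median was -0.34 (camera adjusted p = 0.00911, and adjusted p = 0.664 with an estimated correlation). The 3 were March1, a ubiquitin ligase that removes MHC class II from the surface (-0.93), and the class II genes H2-Ob (-0.67) and H2-Eb2 (-0.85). Cd40 had -0.34 (edgeR adjusted p = 0.0683). With GC offsets Bank1 had a log2 fold change of -0.14 (edgeR adjusted p = 0.412) and Ms4a1 one of -0.82 (edgeR adjusted p = 0.0136). The class II list lost its call with the stricter filter and against DKO replicates 1 and 2 alone (camera adjusted p = 0.103 and 0.0725). Without IL13RA1KO_DKO replicate 2 the calls of Cd83, Fcrla and H2-Ob were lost (edgeR adjusted p = 0.0619, 0.134 and 0.0619). Fcrla also lost its call without IL13RA1KO_DKO replicates 1 or 3 or DKO replicates 1 or 4 (edgeR adjusted p = 0.0518 to 0.0676), and Cd40 passed without DKO replicate 2 (0.0169) and with GC offsets (-0.40, edgeR adjusted p = 0.0497).

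The markers that define age-associated B cells did not pass as a group. Whether cells were sorted on such markers is not known. Such a sort could hold markers like Itgax and Itgam alike, so their values cannot tell whether these cells differed in number. Of 24 genes known to be high in these cells none rose and 2 fell (1 when adjusted over the list alone). The median log2 fold change was -0.04 (camera adjusted p = 0.618). With the macrophage score as a covariate the list of high genes had a median of -0.32 and passed (camera adjusted p = 0.0296), as it did with GC offsets and the covariate (-0.34, camera adjusted p = 0.0106). The integrin genes Itgax (456 ± 87.6 against 499 ± 59.6 CPM, log2 fold change -0.13, SE 0.16) and Itgam (-0.28, SE 0.19), the transcription factor gene Zeb2 (-0.12, SE 0.14) and the receptor gene Fcrl5 (-0.01, SE 0.18) did not pass, with edgeR adjusted p from 0.324 to 0.978. Fcrl5 had positive values in 8 of 22 alternatives, Zeb2 in 2, Itgax (0.015 without IL13RA1KO_DKO replicate 1) and Itgam in 1 each. Tbx21, which encodes the transcription factor T-bet, fell from 212 ± 48.5 to 137 ± 11.2 CPM (-0.63, SE 0.18, edgeR adjusted p = 0.0471). Fgl2 fell from 561 ± 157 to 277 ± 30.0 CPM (-1.02, SE 0.23, edgeR adjusted p = 0.0168). Fas and Ahnak had -0.42 and 1.03 (edgeR adjusted p = 0.0543 and 0.0803). Of 12 genes known to be low in age-associated B cells 2 fell (7 when adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.0236, and adjusted p = 0.524 with an estimated correlation). The desaturase gene Scd1 was among those that fell (-0.80). Il4ra and Bach2 had -0.30 and -0.67 (edgeR adjusted p = 0.063 and 0.0672). The call of Tbx21 was lost in 12 of 22 alternatives, including without any library but DKO replicate 2 (edgeR adjusted p up to 0.185 without IL13RA1KO_DKO replicate 2). Fgl2 lost its call without IL13RA1KO_DKO replicate 1, 2 or 3 (edgeR adjusted p up to 0.0668) and with GC offsets (0.0994), and Scd1 without IL13RA1KO_DKO replicate 2 (0.0539). The list of low genes lost its call with the stricter filter (camera adjusted p = 0.153), with GC offsets and no DKO replicate 2 (0.0581) and without DKO replicate 2 (0.0705). With the macrophage score as a covariate the list of low genes had a median of -0.32 (camera adjusted p = 0.134). For both lists that fit can hardly tell the score from the group. Without DKO replicate 2 Fas, Ahnak, Il4ra and Bach2 passed (edgeR adjusted p = 0.00965, 0.00168, 0.0273 and 0.0454), Bach2 also without DKO replicate 1 (0.0472). Il4ra passed with GC offsets (-0.48, edgeR adjusted p = 0.0147).

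Genes of the IL-4 and IL-13 pathway did not shift as a group. Of 16 receptor and JAK-STAT genes 1 fell (none when adjusted over the list alone), with a median log2 fold change of -0.06 (camera adjusted p = 0.613). Socs1, an inhibitor of cytokine signalling, fell from 26.1 ± 12.5 to 10.2 ± 1.02 CPM (-1.35, SE 0.34, edgeR adjusted p = 0.0296). Il4ra had 289 ± 3.53 against 356 ± 5.82 CPM, and Tyk2 and Socs3 had 0.37 and -0.57 (edgeR adjusted p = 0.0815 and 0.18). Of 24 genes induced by IL-4 in B cells 2 rose and 1 fell (1 and 1 when adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.89). The genes that rose were the chemokine gene Ccl22 (9.94 ± 7.84 to 63.9 ± 20.1 CPM, 2.69, SE 0.57, edgeR adjusted p = 0.0183) and Myc (0.58, edgeR adjusted p = 0.0443). Without IL13RA1KO_DKO replicate 2 the calls of Socs1, Ccl22 and Myc were lost (edgeR adjusted p = 0.124, 0.0772 and 0.122). Socs1 also lost its call without the other IL13RA1KO_DKO replicates or DKO replicate 3, Myc without IL13RA1KO_DKO replicate 1 or DKO replicates 3 or 4 and with GC offsets (edgeR adjusted p = 0.0669 to 0.159). Ccl22 lost its call without DKO replicates 2 or 4 (edgeR adjusted p = 0.051 and 0.0524). The receptor and JAK-STAT list passed with GC and length offsets (median -0.21, camera adjusted p = 0.0289). Tyk2 passed without DKO replicates 1 or 2 (edgeR adjusted p = 0.0418 and 0.0473).

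Genes of the interferon-gamma response were lower on balance in the libraries labelled IL13RA1KO_DKO, where the macrophage and NK cell genes were higher. Of 30 such genes 6 fell and 1 rose (7 and 2 when adjusted over the list alone). The median log2 fold change was -0.29 (camera adjusted p = 0.0317, and adjusted p = 0.779 with an estimated correlation). The GTPase genes Iigp1 (-1.04) and Irgm1 (-0.65) and Socs1 (-1.35) fell, and the chemokine gene Cxcl9 rose (1.14). The list lost its call without IL13RA1KO_DKO replicates 2 or 3, DKO replicates 1 or 2 (camera adjusted p = 0.0538, 0.0509, 0.108 and 0.0629), and against DKO replicates 3 and 4 alone (0.347). The stricter filter and limma-voom also ended it (camera adjusted p = 0.153 and 0.0588). Iigp1 lost its call with GC offsets (-0.63, edgeR adjusted p = 0.116), and Iigp1 and Irgm1 without IL13RA1KO_DKO replicates 2 (0.0756 and 0.135) or 3 (0.051 and 0.0768). Cxcl9 lost its call without IL13RA1KO_DKO replicates 1 or 2 or DKO replicates 1 or 3 (edgeR adjusted p = 0.0824, 0.166, 0.0707 and 0.0893). With the macrophage score as a covariate the log2 fold change of Cxcl9 was -0.54 and the list had a median of -0.415 (camera adjusted p = 0.00728). That fit can hardly tell the score from the group.

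NF-kB targets, immediate-early genes and germinal centre genes held members that went both ways. Of 28 NF-kB targets 5 rose and 2 fell (9 and 3 when adjusted over the list alone), with a median log2 fold change of 0.06 (camera adjusted p = 0.272). Tnfaip2 (2.84, SE 0.39, edgeR adjusted p = 0.00357), Il6 (2.21) and Ccl3 (2.51) rose, the last 2 to 1.05 and 3.39 CPM. Tnfaip2 had 30.8 CPM in IL13RA1KO_DKO replicate 2, the library highest in macrophage genes, against 13.8 and 12.4 CPM in replicates 1 and 3. Its log2 fold change was 0.47 with the macrophage score as a covariate, a fit that can hardly tell the score from the group. The subunit gene Rel fell (147 ± 10.1 to 85.3 ± 8.42 CPM, -0.79, SE 0.12, edgeR adjusted p = 0.00392). Of 31 immediate-early and dissociation stress genes 4 rose and 2 fell (6 and 3 when adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.181). Among these were Klf4 (2.95), Atf3 (1.93), Jun (1.01) and Btg2 (-0.77). Of 19 germinal centre genes 2 rose and 2 fell (2 and 6 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.384). The plexin gene Plxnb2 rose from 68.8 ± 13.2 to 160 ± 36.6 CPM (1.22, SE 0.19, edgeR adjusted p = 0.0046), and Efnb1 rose (0.72). Cd38 (793 ± 71.3 to 473 ± 4.09 CPM, -0.75, SE 0.11, edgeR adjusted p = 0.0042) and the transcriptional repressor gene Bcl6 (-0.58) fell. Cd38 is low on germinal centre B cells of mice, so its fall does not speak for fewer transcripts of such cells. With GC offsets Cd38 had -0.44 (edgeR adjusted p = 0.0345). The immediate-early list passed without IL13RA1KO_DKO replicate 3 (median 0.47, camera adjusted p = 0.00207) and without DKO replicates 1 or 2 (0.0376 and 0.0205). Without IL13RA1KO_DKO replicate 2 the calls of Atf3, Jun, Btg2, Efnb1 and Bcl6 were lost (edgeR adjusted p = 0.0518, 0.0707, 0.0721, 0.0911 and 0.178). Jun, Efnb1 and Bcl6 also lost theirs without replicate 1 of that group (edgeR adjusted p = 0.0563, 0.0703 and 0.0996), Btg2 and Bcl6 without its replicate 3 (0.0539 and 0.0827), and Bcl6 without DKO replicates 3 or 4 (0.0917 and 0.0568). Efnb1 lost its call with GC offsets (edgeR adjusted p = 0.0565).

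Ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation were lower. Of 77 ribosomal protein genes 14 fell and none rose (15 fell when adjusted over the list alone). The median log2 fold change was -0.40 (camera adjusted p = 1.15e-04, and adjusted p = 0.589 with an estimated correlation). Rpl22l1 fell from 85.8 ± 13.9 to 38.7 ± 3.28 CPM (-1.15, SE 0.15, edgeR adjusted p = 0.00303) and Rpl35 from 108 ± 27.3 to 33.4 ± 4.83 CPM (-1.70, SE 0.22, edgeR adjusted p = 0.00312). Rps21 fell from 535 ± 200 to 199 ± 11.4 CPM (-1.43, SE 0.25, edgeR adjusted p = 0.00697), and Rpl3l had 0, 1 and 0 counts in the libraries labelled IL13RA1KO_DKO and 24, 11, 14 and 23 in the DKO libraries. Near-identical stretches in other annotated genes were found for 72 of the 77 genes and for 13 of the 14 that fell, so that the authors' counting could have split their reads. Ribosomal protein genes took 1.89 to 2.07% of counts in the libraries labelled IL13RA1KO_DKO and 2.08 to 3.22% in DKO. Of 30 oxidative phosphorylation genes 2 fell, the cytochrome c oxidase genes Cox5a (-0.82) and Cox6c (-0.59), and 1 fell when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 0.0113, and adjusted p = 0.844 with an estimated correlation). Cycs and Cox8a had -1.31 and -0.65 (edgeR adjusted p = 0.0561 and 0.108), and Cox6c and Cycs share near-identical stretches with other genes. The oxidative phosphorylation list lost its call without DKO replicate 3, against DKO replicates 1 and 2 alone and with the stricter filter (camera adjusted p = 0.0501, 0.18 and 0.162). Cox5a lost its call without IL13RA1KO_DKO replicate 2 and with GC offsets (edgeR adjusted p = 0.0721 and 0.0804), and Cox6c without any library but DKO replicate 2 (up to 0.178 without IL13RA1KO_DKO replicate 2) and with GC offsets (0.0548). Cycs passed without DKO replicates 1 or 2 (edgeR adjusted p = 0.046 and 0.0273) and Cox8a without DKO replicate 2 (0.00464) and with GC offsets (-0.77, 0.0394). In the libraries where these lists were lower the macrophage and NK cell genes were higher. With the macrophage score as a covariate the ribosomal protein list had a median of -0.11 (camera adjusted p = 0.104) and the oxidative phosphorylation list one of -0.012 (0.954). That fit can hardly tell the score from the group, so the lost calls do not show that macrophage RNA accounts for the falls.

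**Figure D4:**
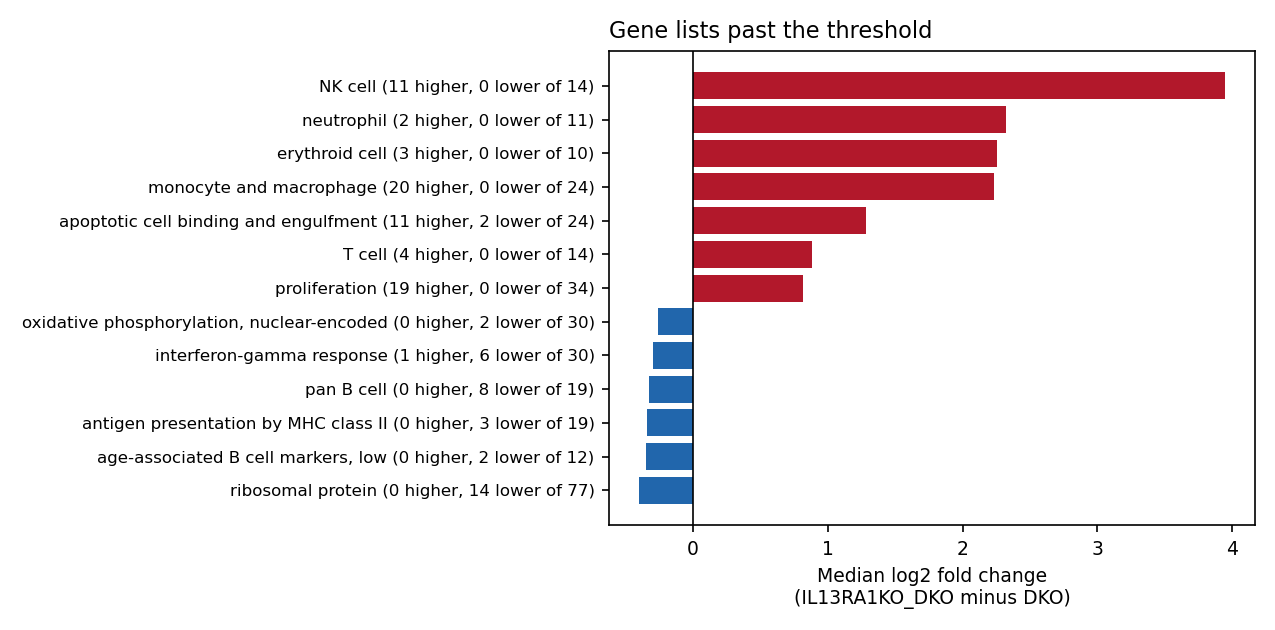
Median log2 fold change (IL13RA1KO_DKO minus DKO, x axis) of the 13 gene lists past the camera threshold, with the number of genes higher and lower of those tested beside each name. The bars run from 3.95 for NK cell genes to -0.40 for ribosomal protein genes, with 7 lists up and 6 down.

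The camera calls of 13 of 34 lists used a preset correlation between genes of 0.01, and none of them held with an estimated correlation. By fry, which tests a list by itself, 5 of the 13 passed (monocyte and macrophage, engulfment, proliferation, pan B cell and low age-associated B cell markers). The other 8 had fry adjusted p from 0.0856 to 0.283. Dendritic cell genes and genes of cytokines and receptors of B cells passed fry (adjusted p = 0.0491 each) and not camera (adjusted p = 0.0582 and 0.196). The 14 tested lists not described had camera adjusted p of 0.0582 or more.

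The shares of Ighg3 and Igha among immunoglobulin heavy chain counts had higher means in the libraries labelled IL13RA1KO_DKO, but no share passed adjustment. Ighg3 made up 4.30 ± 0.341% of heavy chain constant region counts there (SD, n = 3) and 1.60 ± 0.799% in DKO (SD, n = 4), and Igha made up 4.35 ± 1.34% and 1.53 ± 1.08%. For both genes the values of the groups did not overlap, and the exact two-sided permutation p was 0.0571, the smallest the design allows, and 0.229 after adjustment over 8 genes. Among switched classes alone, without Ighm and Ighd, the groups overlapped for Ighg3 (16 to 23.3% and 5.93 to 19.7%) and for Igha (16.2 to 22.2% and 5.79 to 17.8%). Ighm was the largest class at 75 ± 3.35% and 82.8 ± 5.10% (exact permutation p = 0.114, adjusted 0.229), and Ighd made up 1.80 ± 0.734% and 3.36 ± 1.16% (exact permutation p = 0.114, adjusted 0.229). Ighg2b (10.5 ± 3.58% and 6.69 ± 2.26%), Ighg2c (3.24 ± 2.56% and 2.33 ± 0.897%), Ighg1 (0.823 ± 0.384% and 1.64 ± 1.17%) and Ighe (0.0169 ± 0.00463% and 0.0459 ± 0.0542%) had exact permutation p from 0.171 to 0.629. Among switched classes alone Ighg1 made up 3.51 ± 1.37% and 11.9 ± 7.16% and Ighe 0.0754 ± 0.0267% and 0.330 ± 0.342% (adjusted exact permutation p = 0.343 each). The shares rest on 971903 to 2458368 counts per library.

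Per gene, Ighg3 rose with a log2 fold change of 1.65 (SE 0.31, edgeR adjusted p = 0.00947) and Igha with 1.80 (SE 0.45, edgeR adjusted p = 0.0321). The call of Ighg3 was lost in 2 of 21 alternatives. Ighg2b rose with 0.95 (SE 0.27, edgeR adjusted p = 0.0429), while Ighd had -0.71 (edgeR adjusted p = 0.0513). The list of 8 constant region genes had a median of 0.37 with 3 higher (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.359). The median was -0.18 without IL13RA1KO_DKO replicate 1 and -0.076 with limma-voom. The calls of Igha and Ighg2b were lost without IL13RA1KO_DKO replicates 1 (edgeR adjusted p = 0.0724 and 0.108) or 2 (0.118 and 0.168) and DKO replicates 3 (0.077 and 0.0811) or 4 (0.0843 and 0.107), and that of Ighg2b without DKO replicate 1 (0.0937). Both were also lost with GC offsets (edgeR adjusted p = 0.0514 and 0.0674). With the macrophage score as a covariate, in a fit that can hardly tell it from the group, Igha had a log2 fold change of 0.10 and Ighg2b one of -0.42. Ighd passed without IL13RA1KO_DKO replicate 3 or DKO replicate 1 (edgeR adjusted p = 0.0458 and 0.0362). The share of Ighg2c was lower than in DKO, by -0.40 percentage points, without IL13RA1KO_DKO replicate 1.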

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

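The leave-one-out ranges, the comparisons of T cell, NK cell and stromal with macrophage genes, the medians of GC deciles without gene families, the count of macrophage genes that rose, the runs with GC offsets or the macrophage covariate, and the splits with GC and length offsets were tests chosen after the results were seen.

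Among 140 values in the 4 DKO libraries, 5 lay far from the other 3 by Dixon's ratio, where chance gives about 5% of values. Expression relative to each gene's mean over the 7 libraries had a correlation with gene length of 0.404 in DKO replicate 2 and -0.25 to -0.212 in the others. Igha made up 3.14% of constant region counts in DKO replicate 2 and 0.814 to 1.21% in the others. Ighe made up 0.127% in DKO replicate 3 and 0.0140 to 0.0238% in the others. The mean log2 CPM of the IL-4 and IL-13 receptor and JAK-STAT list was 6.67 in DKO replicate 1 and 6.42 to 6.46 in the others. Rps21 had 831 CPM in DKO replicate 1 and 413 to 482 CPM in the others.

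The number of genes past the edgeR threshold does not by itself exclude chance. Of the 35 splits of the 7 libraries into 3 and 4, 2 gave at least 2196 genes, the real split with 2196 and the split of DKO replicates 1, 3 and 4 from the other libraries, with 2278, the highest of the others. That split differs from the real one in the place of DKO replicate 2, whose title code no other library shares, and with GC and length offsets the counts were 1999 and 1992. The other 33 splits gave 0 genes. Without DKO replicate 2 the comparison of the groups gave 4346 genes, which points to a structure in which that library stands apart.

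Monocyte and macrophage genes were higher in the libraries labelled IL13RA1KO_DKO, and a GC content trend was argued against, since with GC offsets the list kept a median log2 fold change of 2.11 (1.67 to 2.41 with a library left out). A lower share of B cell RNA alone would raise markers of all other cell types alike. The markers moved apart, with list medians of 3.95 for NK cell, 2.24 for macrophage, 0.89 for T cell and 0.49 for 4 stromal and endothelial genes (2.76, 1.76, 0.34 and 0.33 without IL13RA1KO_DKO replicate 2, with 5 stromal and endothelial genes). This does not exclude a lower share, since genes that B cells also express would rise less. Only 2 of 13 T cell genes averaged at least 10 CPM in the higher group. Against the mean of 24 macrophage genes, 13 T cell genes differed by -0.93 (permutation p = 0.0167 over 100000 resamples, at most 0.0249 with a library left out), 5 T cell genes averaging at least 100 counts by -1.37 (exact permutation p = 0.0105, 22 macrophage genes) and 14 NK cell genes by 1.43 (permutation p = 0.0049, at most 0.0361), across genes that are not independent. More RNA from macrophages and other non-B cells remains a candidate explanation, with 20 of 24 macrophage genes higher, among them Hmox1 at 861 CPM, Axl at 362 CPM and Cd5l at 306 CPM, but that count cannot separate it from higher expression per cell. The labels state no sort that would remove such cells. T cell genes at 0.204 to 1.94 log2 CPM, against 9.32 to 9.83 for genes shared by all B cells, argue against RNA of unsorted spleen. Whether the 2 groups were sorted alike is not known, only the DKO titles carry the tag ABC, and the genotype itself stays open.

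Genes of low GC content were lower in the libraries labelled IL13RA1KO_DKO. Leaving out immunoglobulin, mitochondrially encoded and ribosomal protein genes kept 2144 of 2196 calls and gave 1151 lower genes, which decides nothing because it moved so little. Counts taken by these families would shift all other genes alike. They were argued against by the spread between GC deciles, with medians of -0.46 in the lowest and 0.13 in the highest. The difference was -0.58 without the families (-0.65 to -0.51 with a library left out), but leaving them out could hardly move it. A single DKO title code was also argued against. The lowest decile by GC had a median of -0.454 against DKO replicates 3 and 4 and of -0.447 against DKO replicates 1 and 2. A GC content trend between libraries and the genotype cannot be told apart for these genes: with GC offsets 615 of 1179 lower genes (52.2%) were still lower, and the share ran from 24.0% to 74.0% with a library left out. Expression relative to each gene's mean over the 7 libraries had a correlation with GC content of 0.194 to 0.333 in the libraries labelled IL13RA1KO_DKO and -0.371 to -0.01 in DKO. These relative values do not give each library's own GC bias. The title codes and letters that part the groups keep library preparation open.

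Proliferation genes were higher in the libraries labelled IL13RA1KO_DKO. A GC content trend was argued against, since the list kept a median of 0.85 with GC offsets (0.71 to 1.05 with a library left out). With the macrophage score as a covariate the median was 1.30 (1.06 to 1.81), but that score had a correlation of 0.927 with the group over the 7 libraries. The covariate leaves little of the group difference to measure, so the fit does not decide whether more RNA from macrophages is the whole cause. The macrophage list itself had a median of -0.026 in that fit, which was set in advance because the score is the mean of that list. The genotype stays open and untested as a source of the rise, and the title code is confounded with it.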

How the results depend on the processing

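The settings with GC offsets, with GC and length offsets and with the macrophage covariate were tests chosen after the data were seen. With 1 library left out in turn, the edgeR calls ranged from 899 to 4346 genes (466 to 2150 higher, 433 to 2196 lower, 576 to 1475 with an absolute log2 fold change of at least 1), with the lowest numbers without IL13RA1KO_DKO replicate 2 and the highest without DKO replicate 2. Of 100 named genes between 6 (without DKO replicate 2) and 31 (without IL13RA1KO_DKO replicate 2) lost a call. With GC offsets 12 lost and 3 gained a call, and without a low-count filter 15 and 4. There were 9 lost and 9 gained with only DKO replicates 3 and 4, and 38 lost with only DKO replicates 1 and 2. The libraries kept their separation in distance, from 0.53 to 1.16, where no such design can pass the threshold. Il13ra1 ranged from -0.38 to 0.13, Itgax from -0.21 to 0.015, Fcrl5 from -0.13 to 0.14, the list of high age-associated B cell markers from -0.098 to 0.009, the IL-4-induced list from -0.16 to -0.03 and the Ighg2c share difference from -0.399 to 2.15 percentage points. In switched classes alone the difference in immunoglobulin heavy chain constant region share of Ighg2b was -3.50 points and that of Ighg2c -2.11, since Ighm and Ighd leave the denominator.

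Counts of genes moved by over 1.5 times with limma-voom (4770, with 2415 higher, 2355 lower and 1577 of at least 1), the stricter filter (1456, with 634 higher and 384 of at least 1, where fewer genes were tested), only DKO replicates 3 and 4 (4601, with 2347, 2254 and 1605), only DKO replicates 1 and 2 (868, with 384, 484 and 526) and GC offsets without DKO replicate 2 (4098, with 1994 and 2104). The replicate numbers did not pair the libraries (same-number correlations 0.19, -0.051 and 0.083, with replicates 2 and 3 of IL13RA1KO_DKO closest to other numbers), and the fit with the replicate block called 1110 genes (631 higher, 479 lower), and the class II and low age-associated marker lists had camera adjusted p = 0.0513 each. The number of gene lists past the threshold went from 13 to 5 with the stricter filter, where fewer lists had enough genes, 0 with an estimated correlation and 6 with the macrophage covariate, 2 of them among the 13. The list of high age-associated B cell markers gained a call there (-0.32, camera adjusted p = 0.0296, and with GC offsets -0.34, 0.0106). Values near 0 changed sign: Il13ra1 was 0.16 with the replicate block, 0.37 with only DKO replicates 1 and 2, 0.065 with GC offsets and 0.16 with GC and length offsets. Fcrl5 was 0.10 with limma-voom, 0.064 with the stricter filter, 0.0093 with the block, 0.21 with only DKO replicates 3 and 4, 0.051 with upper quartile and 0.073 with total counts. Itgam was 0.020 with only DKO replicates 3 and 4, and Zeb2 0.22 with GC offsets and 0.26 with GC offsets without DKO replicate 2. The high marker list was 0.035 with the stricter filter and 0.006 with only DKO replicates 3 and 4, and the camera direction of the IL-4-induced list turned in 5 of 22 alternatives, at medians of -0.073 (stricter filter), -0.038 (only DKO replicates 1 and 2), -0.03 (without IL13RA1KO_DKO replicate 3), -0.121 (without DKO replicate 1) and -0.038 (without DKO replicate 3). The targeted gene Def6 passed with DESeq2 (-0.84), no filter (-0.84) and GC offsets without DKO replicate 2 (-0.88). The median of the heavy chain constant region list was -0.18 without IL13RA1KO_DKO replicate 1 and -0.076 with limma-voom. The cause of these shifts was not tested.

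With the macrophage covariate, alone or with GC offsets, edgeR called 0 genes (0 higher, 0 lower, 0 of at least 1), with 449 and 320 at an unadjusted p under 0.05, where DESeq2 without it called 2983 and limma-voom 4770. The score had a correlation of 0.927 with the group, so that little of the group difference was left to estimate. Log2 fold changes of the opposite sign, alone and then with GC offsets, were 0.071 and 0.31 for Il13ra1, -1.04 and -1.20 for Ptgis, -0.95 and -1.08 for Nkg7, 0.10 and 0.22 for Lifr, -0.42 and -0.49 for Ighg2b, 0.21 and 0.25 for Ighd, -0.54 and -0.42 for Cxcl9, -0.31 and -0.27 for Ccl3, -0.19 and -0.33 for Jun, -0.068 and -0.22 for Axl, 0.54 and 0.82 for Cycs, -0.82 and -0.75 for Cd247, -1.92 and -1.88 for Cxcr2, -1.38 and -1.38 for Il1b, -1.24 and -1.43 for Mmp9, -0.61 and -0.64 for Car2 and -0.0083 and -0.092 for Hbb-bt, with -0.10 for Klrk1 alone, and -0.011 for Tyk2 and -0.017 for Igha with GC offsets. List medians were -0.37 and -0.14 for T cells, 0.48 and 0.46 for germinal centre, -0.19 and -0.25 for immediate-early, -0.026 and -0.12 for macrophages and -3.14 and -3.23 for neutrophils, with 0.018 for NK cells, -0.003 for IL-4-induced and -0.012 for oxidative phosphorylation genes alone, and -0.058 for NF-kB targets with GC offsets. Low levels limit the T cell, neutrophil and erythroid genes, most of which averaged under 10 CPM in both groups.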

Other observations

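The tests of the segment and light chain shares, and the values of Gapdh, were chosen after the results were seen.

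The heavy chain variable segment with the most counts was Ighv3-6 in all 4 DKO libraries, at 6.61, 8.09, 9.22 and 9.43% of variable segment counts in replicates 1 to 4. In the libraries labelled IL13RA1KO_DKO it was Ighv1-26 in replicate 1 (8.93%, 95% Wilson interval 8.82 to 9.05%), Ighv1-47 in replicate 2 (12.2%, 12 to 12.3%) and Ighv1-26 in replicate 3 (6.79%, 6.67 to 6.92%), where the intervals cover counting error only. The share of the leading segment did not separate the groups (9.31 ± 2.72% and 8.34 ± 1.30% SD, exact two-sided permutation p = 0.629), nor did that of the 10 leading segments (45.7 ± 5.64% and 44.8 ± 2.47%, exact two-sided permutation p = 0.743). Lambda chains made up 7.06 ± 1.59% and 6.93 ± 1.87% of light chain counts (exact two-sided permutation p = 1.0).

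Gapdh, chosen after its values were seen, had 53.3 and 42.4 CPM in DKO replicates 1 and 2, 2.44 and 2.66 CPM in DKO replicates 3 and 4, and 6.31, 6.39 and 6.85 CPM in the libraries labelled IL13RA1KO_DKO (log2 fold change -1.95, SE 1.10, edgeR adjusted p = 0.27). Rps25 parted the DKO libraries in the same way. Gapdh shares a near-identical stretch with 140 other annotated genes, so that its counts are uncertain.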
